A study of Mus musculus with 6 samples.

How the data were processed

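RNA was measured by sequencing in 6 libraries of mouse neural progenitor cells. Per the labels' protocols, total RNA was isolated on silica columns, and cDNA libraries were made with a kit for ultra-low input or with a TruSeq kit; which library was made with which kit is not given in the sources used here. The submitters' processing notes name STAR and featureCounts, without versions, and the builds GRCm38.p6 and mm10. The deposited file held whole-number counts per gene for the 6 libraries, not normalized, in 42365 rows of Ensembl gene IDs, the smallest with a sum of 2. Settings for strand and for reads that map to several places are not given in the sources used here. Pseudogene copies of mitochondrial genes carried counts, so reads of near-identical genes may be split or counted more than once, and overlapping or antisense genes cannot be told apart.

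The columns were matched to the samples by name, and groups were taken from the sample titles: 2 parental libraries, 2 of knockout clone 1 and 2 of knockout clone 2. Gene symbols and coordinates came from a GENCODE annotation of GRCm38, the build the notes name; 41869 of the 42365 IDs were found in it, 41112 with the same version. The IDs not found held 0.603% to 0.83% of the counts of a library and stayed in the tests. Totals per library ran from 58871554 to 69530032 counts, and mitochondrial genes took 5.37% to 6.86%. Reads are not independent molecules, so precision is judged from the spread between libraries.

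Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count of 10), libraries were scaled by TMM, and the robust quasi-likelihood test was applied with Benjamini-Hochberg adjustment at 0.05. For labelled knockout against parental cells, the 2 libraries of each clone were added, so that the fit had 4 columns (2 clones and 2 parental libraries) and 2 residual degrees of freedom. Each clone against parental, and the clones against each other, were contrasts of 1 fit of 6 libraries in 3 groups, with 3 residual degrees of freedom; it treats libraries of a clone as replicates. The SE of a log2 fold change is its size divided by the square root of the F statistic. A fold is 2 to the power of the size of the log2 fold change. CPM used TMM-scaled library sizes, except for satellite gene models and receptor genes, whose CPM used the library totals. Correlations and principal components used log2 CPM with a prior count of 2.

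For the lists, 48 sets of genes were fixed before the data were examined, with 1112 of their 1120 genes found. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 48 lists. The genes named in the text followed a rule fixed at the same time: for labelled knockout against parental, the 12 called genes with the largest and the 12 with the smallest log2 fold change among named genes with a mean of at least 5 CPM and all 4 labelled knockout libraries on the same side of both parental ones; by the same rule 10 and 10 for clone 2 against clone 1 and 5 and 5 for each clone against parental; and up to 4 members of each list described, those with the smallest adjusted p. Some genes that this rule names are not reported here. The genes of a MAPK activity score, satellite gene models and receptor genes in the closing section were chosen after their values were seen.

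The tests were tried on simulated data made from the real means and library sizes. With the clones as replicates (24506 genes), 2.99% of genes changed 1.5-fold were called, 23.1% of those changed 2-fold and 71.2% of those changed 4-fold, with 40 calls among 48612 unchanged genes. For clone 1 against parental (23400 genes) the shares were 54.5%, 61.2% and 89.4%, with 21 calls among 46400. Far fewer genes were changed than were called in the real data, which makes the adjusted threshold stricter in the simulation. Of 20 unchanged lists, 0 were called in a simulation of the 3-group fit. Its genes were drawn independently and its lists at random. It therefore cannot show how the preset correlation serves lists of correlated genes. Overlap between the clones was set beside 20 simulations of unchanged clones. The alternatives were other scalings (DESeq2 size factors, upper quartile), no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom with the clone as a random block, other units of replication, a replicate block, an effect of at least 1 on the log2 scale, and leaving out each library in turn.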

Results

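RNA from mouse neural progenitor cells (NPC), cultured cells that can give rise to neurons and glia, was sequenced to compare wild-type cells with cells labelled knockout. The genotype is as the labels give it, so the clones are called labelled knockout throughout. The 6 libraries fell into 3 groups of 2: parental cells, knockout clone 1 and knockout clone 2. The parental libraries held 63879208 and 58871554 counts, those of clone 1 held 66955560 and 69530032, and those of clone 2 held 65345036 and 60924858. Values after ± are the SD of the 2 libraries of a group (n = 2) in CPM (counts scaled to TMM-scaled library sizes). After a log2 fold change, values after ± are its standard error (SE). The titles call the parental libraries clone 1 and clone 2 and give 2 libraries for each knockout clone. Whether the parental clones are independent, or the libraries of a knockout clone came from separate cultures, is not given in the sources used here. In the fit of single libraries the p-values thus measure the spread between these libraries, which may be technical. With the clones as replicates, they measure a spread that pools the clone difference with the parental library difference. That fit assumes that clones and parental libraries vary alike. A count was found for 37678 and 37419 genes in the parental libraries, 32686 and 32130 in clone 1, and 31262 and 30747 in clone 2.

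Libraries of a group lay close together and the groups lay apart. Across genes, the log2 CPM of 2 libraries of a group correlated at 0.992 to 0.993, the 2 clones at 0.978 to 0.981, and parental with labelled knockout libraries at 0.933 to 0.936; genes are not independent replicates. The leading principal component held 73.3% of the variance and separated parental from labelled knockout libraries, and the next held 16.5% and separated the clones. The chi-square of the counts per gene was 3.48 for the parental pair, 22.1 for clone 1 and 4.92 for clone 2, so no pair matched within sampling noise.

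**Figure D1:**
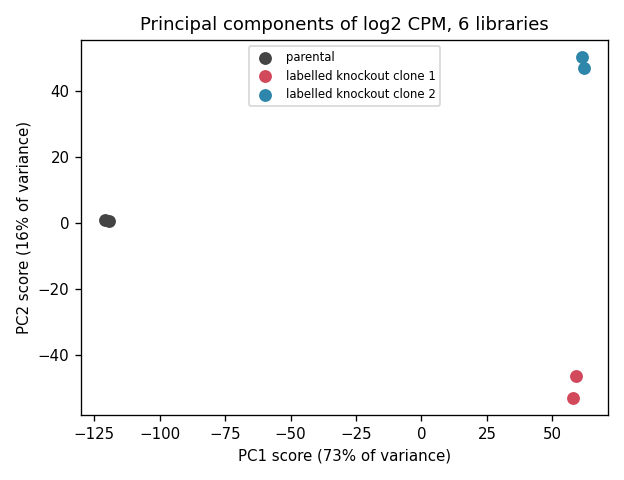
Scores of the 6 libraries on the leading principal components of log2 CPM, with the share of variance on each axis; each point is 1 library, coloured by group. PC1 (73.3%) separates parental libraries, at -121 to -119, from labelled knockout libraries, at 57.8 to 62, and PC2 (16.5%) separates the clones.

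The main comparison asked how the state of the cells differed between labelled knockout and parental cells, with the 2 clones as the replicates of the genotype. Genes of mitosis led those that were higher. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose 306-fold. It was at 0.234 ± 0.0434 CPM in the parental libraries, 90.7 ± 3.76 in clone 1 and 51.2 ± 1.43 in clone 2. Ccnb1, which encodes cyclin B1, rose by 7.65 (SE 0.45, adjusted p = 0.000667) on the log2 scale, and the proliferation marker Mki67 by 6.67 (SE 0.37, adjusted p = 0.000592), from 3.91 to 504 and 277 CPM. Astrocyte genes were among those with the largest falls. Gfap, the intermediate filament of astrocytes, was at 2691 ± 39.9 CPM in the parental libraries, 1.59 ± 0.0858 in clone 1 and 9.7 ± 0.296 in clone 2, and fell by 8.86 on the log2 scale (SE 1.17, adjusted p = 0.0121).

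Most of the other genes with the largest rises were also of mitosis or its control: Pbk (7.78 ± 0.42, log2 fold change and SE), Cdca2 (7.38 ± 0.34), Nek2 (7.37 ± 0.28), Hmmr (7.19 ± 0.16), Aspm (7.01 ± 0.33), Depdc1a (6.82 ± 0.62), Bub1 (6.50 ± 0.62) and Cenpf (6.44 ± 0.28). The DNA helicase gene Pif1 rose by 6.38 ± 0.26. The adjusted p of these genes ran from 0.00013 for Hmmr to 0.00272 for Bub1. Among the genes with the largest falls, Gja1, which encodes the gap junction protein connexin 43 of astrocytes, dropped from 432 ± 4.84 to 0.556 ± 0.203 and 1.1 ± 0.0559 CPM (-8.996 ± 0.37). Ripply1 (-9.83 ± 0.34), Hspb8 (-8.97 ± 0.79), Lpl (-8.59 ± 0.58), Rgs4 (-8.36 ± 0.22), the oncostatin M receptor gene Osmr (-8.29 ± 0.22), the receptor kinase gene Met (-8.28 ± 0.65), Naaa (-7.93 ± 0.24), Synpo2 (-7.87 ± 0.16) and Afap1l2 (-7.83 ± 0.29) were also among them. Each gene named so far lay on the same side of both parental libraries in all 4 labelled knockout libraries.

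**Figure D2:**
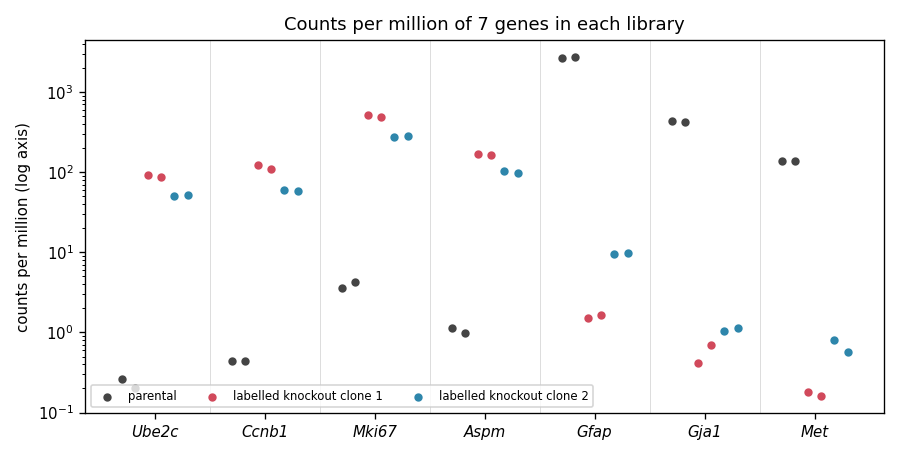
CPM of 7 genes on a log axis, 1 point per library, coloured by group, scaled by TMM. Ube2c, Ccnb1, Mki67 and Aspm lie higher in the 4 labelled knockout libraries, and Gfap, Gja1 and Met lie lower.

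In all, 6532 of 24506 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3187 higher and 3345 lower in the labelled knockout clones, and 4035 of them changed by at least 1 on the log2 scale (1673 higher and 2362 lower). Of the 6532 genes, 6260 (95.8%) were also called in the same direction in each clone tested alone. Both tests use the same libraries, so this overlap is not independent evidence. Without parental library 1 the count was 2544 and without parental library 2 it was 2529, and Gfap, Hspb8 and Met then missed the threshold, with adjusted p from 0.151 to 0.352. The count was 3795 among genes of at least 5 CPM, and 13213 for the averaged clone effect, with libraries as replicates and the clone difference taken out of the residual.

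Cell cycle genes rose as groups. All 30 mitotic genes of the G2/M list rose, with a median log2 fold change of 5.25 (30 higher and 0 lower adjusted over the list alone). Its camera adjusted p was 4.68e-40, and adjusted p = 0.533 with an estimated correlation. Hmmr rose by 7.19 ± 0.16, the topoisomerase gene Top2a by 5.54 ± 0.16 and the kinase genes Aurkb and Plk1 by 6.31 ± 0.25 and 6.18 ± 0.25 on the log2 scale (± SE). Of the 29 genes of DNA replication and G1/S, 27 rose and 2 did not pass (27 adjusted over the list alone), with a median of 1.58. Camera gave this list adjusted p = 1.18e-17, and adjusted p = 0.533 with an estimated correlation. Among them the ribonucleotide reductase gene Rrm2 rose by 3.19 ± 0.15, the replicative helicase genes Mcm5 and Mcm2 by 3.03 ± 0.15 and 2.01 ± 0.12, and E2f1 by 3.07 ± 0.18. A list of RNAs without a poly(A) tail, mostly replication-dependent histone genes, which cells make in S phase, had 26 of 28 members higher (26 adjusted over the list alone) and a median of 2.31. By camera the adjusted p was 1.6e-25, and adjusted p = 0.533 with an estimated correlation. Hist1h2ad rose by 3.46 ± 0.11, Hist1h4d by 1.93 ± 0.086, Hist1h4h by 1.89 ± 0.093 and Hist1h4a by 1.57 ± 0.084. Adding the libraries of a clone hides their spread. In the fit of single libraries the SE in each clone was 0.25 for Hist1h4h and 0.19 for Hist1h4a. For Hist1h2ad and Hist1h4d it was 0.089 and 0.094, close to the SE above. Near-identical histone copies can share reads, so these values are uncertain.

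Sterol synthesis and ribosomal protein genes were higher, and so was the Wnt list by the list test. Of 24 genes of cholesterol synthesis, 20 rose and 4 did not pass (22 higher adjusted over the list alone), with a median of 1.31. The camera test gave adjusted p = 1.62e-14, and adjusted p = 0.533 with an estimated correlation. Insig1, which encodes a brake on sterol synthesis, rose 4.52-fold, and the enzyme genes Dhcr7 and Lss rose 3.37-fold and 2.91-fold. Of 54 ribosomal protein genes, 35 rose (40 adjusted over the list alone), by a median of 0.47. Tested with camera, the list had adjusted p = 4.23e-08, and adjusted p = 0.533 with an estimated correlation. Rpl32 rose by 0.81 ± 0.10, Rpl5 by 0.76 ± 0.098, Rps7 by 0.64 ± 0.083 and Rpl35 by 0.61 ± 0.081. These 4 missed the threshold when either parental library was left out, with adjusted p from 0.0539 to 0.143. In the Wnt list 10 of 21 genes rose and 4 fell (12 higher and 4 lower adjusted over the list alone). For these genes camera gave adjusted p = 0.0143, and adjusted p = 0.566 with an estimated correlation. The Wnt feedback genes Znrf3 and Nkd1 rose by 1.74 ± 0.11 and 2.44 ± 0.16, the receptor gene Fzd9 by 1.60 ± 0.13 and Lgr5 by 2.09 ± 0.17.

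Genes of the integrated stress response and the respiratory chain were higher by the list test with the clones as replicates, but neither list passed in clone 1 alone. In the integrated stress response list 12 of 27 genes rose and 3 fell (14 higher and 3 lower adjusted over the list alone). Its camera adjusted p was 0.012, and adjusted p = 0.75 with an estimated correlation. The serine synthesis gene Psat1 rose by 1.72 ± 0.12 and Stc2 by 2.52 ± 0.24, while Cebpb changed by -2.27 ± 0.15 and Atf3 by -2.49 ± 0.21 on the log2 scale. Of 75 nuclear genes of oxidative phosphorylation, 13 rose and 1 fell (2 higher and 0 lower adjusted over the list alone), with a median of 0.24. Camera gave this list adjusted p = 0.012, and adjusted p = 0.954 with an estimated correlation. With upper quartile scaling 6 rose and 1 fell. Against parental cells clone 1 had 22 of the 75 genes higher and 18 lower (camera adjusted p = 0.921), and clone 2 had 57 higher and 2 lower (camera adjusted p = 0.00035; adjusted p = 0.721 with an estimated correlation). The stress response list had camera adjusted p = 0.356 in clone 1. Atp5c1 rose by 0.63 ± 0.084, Cox7a2 by 0.60 ± 0.086, Ndufc1 by 0.50 ± 0.089 and Uqcrh by 0.70 ± 0.15, and none of these 4 passed without either parental library (adjusted p from 0.0711 to 0.255). The 13 protein genes of mitochondrial DNA had 3 members higher and 10 that did not pass, and their list did not pass the list test. By camera the adjusted p was 0.269, and adjusted p = 0.954 with an estimated correlation.

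Lists of astrocyte, neuronal differentiation, NF-kB and antigen presentation genes were lower. Of 20 astrocyte markers, 11 fell and 1 rose (2 higher and 13 lower adjusted over the list alone), with a median of -1.25. The camera test gave adjusted p = 1.35e-07, and adjusted p = 0.533 with an estimated correlation. The water channel gene Aqp4 dropped from 742 ± 3.86 CPM to 25.2 ± 3.6 and 28.7 ± 0.55, and Apoe from 2821 ± 138 to 287 ± 46 and 239.7 ± 14.9. The angiotensinogen gene Agt changed by -2.92 ± 0.15 on the log2 scale. Of 23 genes of neuronal differentiation, 9 fell and 1 rose (2 higher and 11 lower adjusted over the list alone). Tested with camera, the list had adjusted p = 0.00167, and adjusted p = 0.533 with an estimated correlation. Dcx, expressed in migrating young neurons, changed by -2.80 ± 0.13 on the log2 scale (± SE), Elavl3 by -2.14 ± 0.16, Tubb3 by -2.13 ± 0.16 and Neurog2 by -4.19 ± 0.35. Neurog2 was low in the parental libraries too, at 0.947 CPM. Among 12 tested genes of NF-kB and inflammation, 8 fell and 1 rose (1 higher and 8 lower adjusted over the list alone). For these genes camera gave adjusted p = 0.000914, and adjusted p = 0.533 with an estimated correlation. C3 changed by -3.02 ± 0.24, the chemokine genes Ccl7 and Ccl2 by -5.42 ± 0.47 and -4.00 ± 0.37, and Vcam1 by -1.51 ± 0.15. C3, Ccl7 and Ccl2 were low in the parental libraries too, at 2.13, 1.4 and 0.893 CPM. In the antigen presentation list 4 of 12 genes fell (0 higher and 5 lower adjusted over the list alone). Its camera adjusted p was 0.0286, and adjusted p = 0.533 with an estimated correlation. The 4 were Tapbp (-1.70 ± 0.087), Erap1 (-0.97 ± 0.11), Nlrc5 (-2.12 ± 0.31) and Tap2 (-0.96 ± 0.16). Erap1 and Tap2 missed the threshold without either parental library (adjusted p from 0.0546 to 0.16).

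Genes tied to Parkinson disease, antioxidant genes and imprinted genes were lower as lists. Of 15 tested genes of inherited Parkinson disease, 6 fell and 9 did not pass (0 higher and 9 lower adjusted over the list alone). Camera gave this list adjusted p = 0.012, and adjusted p = 0.533 with an estimated correlation. Pink1, which encodes a kinase that acts on damaged mitochondria, dropped from 259 ± 0.361 CPM to 105 ± 0.631 and 113 ± 0.85 (-1.22, SE 0.09, adjusted p = 0.000886). Uchl1 changed by -3.05 ± 0.15, Fbxo7 by -0.71 ± 0.14 and Dnajc6 by -1.46 ± 0.31; Fbxo7 and Dnajc6 did not pass without either parental library (adjusted p from 0.0789 to 0.155). Dnajc6 was low in the parental libraries too, at 1.03 CPM. In the NRF2 antioxidant list 11 of 25 genes fell and 1 rose (2 higher and 13 lower adjusted over the list alone). By camera the adjusted p was 0.00256, and adjusted p = 0.652 with an estimated correlation. The ferritin gene Fth1 changed by -1.65 ± 0.086 and the glutathione peroxidase genes Gpx4 and Gpx1 by -1.61 ± 0.10 and -1.24 ± 0.09, while the thioredoxin gene Txn1 rose by 2.21 ± 0.19. In the imprinted list 9 of 21 genes fell and 3 rose (3 higher and 9 lower adjusted over the list alone). The camera test gave adjusted p = 0.012, and adjusted p = 0.652 with an estimated correlation. Igf2r changed by -4.84 ± 0.18, H19 by -3.30 ± 0.23, and Plagl1 by -4.54 ± 0.56, while Sgce rose by 0.98 ± 0.13. Without either parental library Plagl1 did not pass (adjusted p of 0.155 and 0.158).

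**Figure D3:**
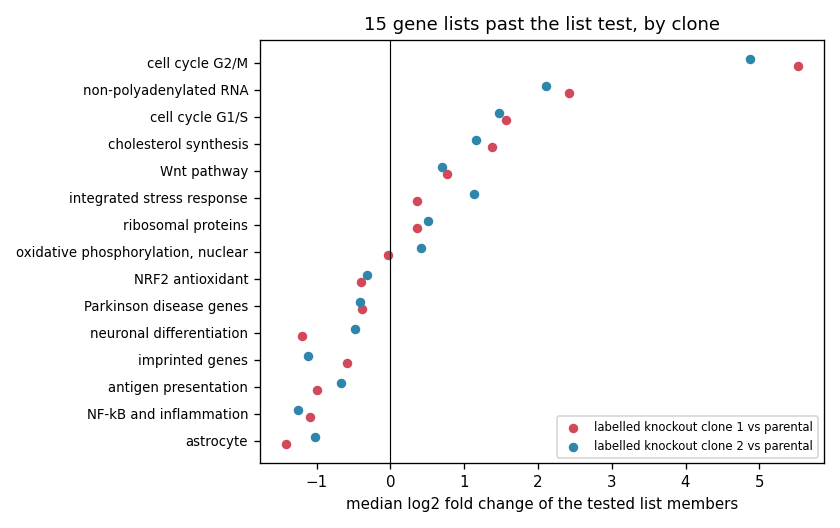
Median log2 fold change against parental libraries over the tested members of the 15 lists past the list test, for clone 1 and clone 2. The G2/M list has the largest medians, 5.53 and 4.88, and the astrocyte list is at -1.42 and -1.02; the nuclear list of oxidative phosphorylation is at -0.032 and 0.42.

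Lists close to the study's subject held members that went both ways. Of 22 genes of neural progenitors and radial glia, 13 rose and 6 fell (13 higher and 6 lower adjusted over the list alone). Tested with camera, the list had adjusted p = 0.144, and adjusted p = 0.64 with an estimated correlation. Sox1 dropped from 60.5 ± 0.0825 CPM to 3.35 ± 0.145 and 3.17 ± 0.239, and Msi1 changed by -1.29 ± 0.082, while Fabp7 and Bcan rose by 1.91 ± 0.087 and 1.68 ± 0.098 on the log2 scale. Of 18 oligodendrocyte lineage genes, 5 rose and 6 fell (6 higher and 7 lower adjusted over the list alone). For these genes camera gave adjusted p = 0.996, and adjusted p = 0.996 with an estimated correlation. Olig1 and Olig2, factors of oligodendrocyte precursors, rose 5.83-fold and 4.29-fold and Nkx2-2 3.73-fold, while Gpr17 changed by -3.75 ± 0.27. Of 14 tested dopaminergic genes, 4 rose and 2 fell (4 higher and 3 lower adjusted over the list alone). Its camera adjusted p was 0.988, and adjusted p = 0.996 with an estimated correlation. En1 changed by -3.44 ± 0.51, and Lmx1b, Foxa1 and En2 rose by 2.25 ± 0.36, 0.97 ± 0.16 and 1.42 ± 0.24; Foxa1 did not pass without either parental library (adjusted p of 0.162 and 0.127), nor En2 without parental library 2 (0.0685). Of 28 genes of mitophagy, 4 rose and 4 fell (5 higher and 5 lower adjusted over the list alone). Camera gave this list adjusted p = 0.988, and adjusted p = 0.996 with an estimated correlation. Besides Pink1, the autophagy receptor gene Sqstm1 changed by -1.01 ± 0.083, and Bnip3 and Bnip3l rose by 1.36 ± 0.13 and 0.83 ± 0.087; Bnip3l did not pass without parental library 2 (adjusted p = 0.0596).

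With the preset correlation of 0.01 between genes, 15 of 48 lists passed camera, 8 higher and 7 lower. With an estimated correlation 0 of 48 passed, 1 at an unadjusted p under 0.05, and fry, which tests whether a list's genes move on balance in 1 direction, called 24.

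Each clone was then compared with the parental libraries in a fit of all 6. In clone 1 the largest rises were in Ube2c (8.58 ± 0.10), Pbk (8.10 ± 0.14), Ccnb1 (8.02 ± 0.10), Cdca2 (7.63 ± 0.14) and Nek2 (7.47 ± 0.19). The largest falls were in the small heat shock gene Hspb8 (-11.22 ± 0.16), Gfap (-10.73 ± 0.068), the Hspb8 partner gene Bag3 (-9.70 ± 0.13), Met (-9.62 ± 0.11) and Ripply1, which had 0 and 2 counts against 1854 and 1783. In clone 2 the largest rises were in Ube2c (7.75 ± 0.11), Pbk (7.28 ± 0.15), Nek2 (7.18 ± 0.20), Ccnb1 (7.06 ± 0.10) and Hmmr (7.06 ± 0.11). Among the largest falls there were those of Ripply1 (-9.24 ± 0.20), Rgs4 (-8.73 ± 0.15), Gja1 (-8.62 ± 0.089) and the lipoprotein lipase gene Lpl, with 0 and 2 counts against 1749 and 1623. Their adjusted p were at most 1.08e-14.

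By edgeR's quasi-likelihood test 12752 of 23400 genes passed in clone 1 (6384 higher and 6368 lower) and 12520 in clone 2 (6243 higher and 6277 lower); 5084 and 5101 of them changed by at least 1 on the log2 scale. Genes called in both clones numbered 4525 higher and 4660 lower, and 490 went opposite ways. Simulated unchanged clones that shared simulated parental libraries gave a mean of 0.05 genes for each. With no gene changed, at most a mean of 0.65 genes per direction was called in clone 1 and 0.75 in clone 2. The simulated overlap was therefore bound to be small, and it cannot show how many shared calls come from sharing the parental libraries. Independent lists of the observed sizes gave 1703.2 higher, 1708.2 lower and 3411.4 opposite. Fold changes of the clones correlated at 0.84 across genes against 0.508 simulated, with a covariance of 1.6 against 0.0399, a difference of 1.56. The 2 parental libraries were not split, since each part would hold 1 library, and part of the excess in shared calls may come from sharing them. Camera passed 14 lists in clone 1 and 19 in clone 2, and 1 in each with an estimated correlation, the G2/M list (adjusted p of 0.0126 and 0.0174).

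The clones were also compared with each other, since both carry the labelled genotype. Evc2 and its neighbour Evc, genes of the primary cilium (GRCm38 chromosome 5, 37338499 to 37425055 and 37289098 to 37336894), were lower in clone 1 than in clone 2. Evc2 had 2 and 3 counts in clone 1 and was at 13.3 ± 0.941 CPM in the parental libraries, 0.0371 ± 0.00934 in clone 1 and 25.8 ± 0.883 in clone 2, higher in clone 2 than in clone 1 by 9.36 (SE 0.18, adjusted p = 1.49e-15), and Evc, at 17 ± 0.628 CPM in the parental libraries, 1.33 ± 0.148 in clone 1 and 43.8 ± 1.4 in clone 2, was higher by 5.04 ± 0.096. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 125 ± 0.288 CPM in the parental libraries, 14.7 ± 1.01 in clone 1 and 289 ± 16.3 in clone 2, a log2 difference of 4.29 (SE 0.06, adjusted p = 4.36e-17). Neuronatin (Nnat), an imprinted gene, was lower in clone 2, at 379 ± 0.841 CPM in the parental libraries, 223 ± 8.73 in clone 1 and 7.79 ± 0.806 in clone 2 (-4.84, SE 0.064, adjusted p = 2.63e-17).

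Other genes with the largest rises from clone 1 to clone 2 were Bag3 (8.13 ± 0.14), the imprinted gene Ndn (6.44 ± 0.28), Spock2 (6.03 ± 0.077), Armcx1 (5.23 ± 0.18), Mxra7 (4.62 ± 0.14), Trp53cor1 (4.28 ± 0.11), the p53-induced long noncoding RNA next to Cdkn1a, and the complex I gene Ndufv3 (4.13 ± 0.066). Lower in clone 2 were Dpp6 (-7.42 ± 0.13), Nrk (-5.98 ± 0.15), Edil3 (-4.30 ± 0.19), Ston2 (-4.20 ± 0.092), Nynrin (-4.01 ± 0.069), the synaptic adhesion gene Nlgn3 (-3.85 ± 0.095), Tubb4a (-3.56 ± 0.12), Sostdc1 (-3.12 ± 0.09) and Tmem132b (-3.11 ± 0.16). Of 23400 genes, 8511 passed edgeR's quasi-likelihood test, 3759 higher and 4752 lower in clone 2, and 1500 changed by at least 1 on the log2 scale.

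Of 23 tested p53 target genes, 16 were higher and 3 lower in clone 2 than in clone 1 (17 higher and 3 lower adjusted over the list alone), with a median of 1.61. By camera the adjusted p was 9.15e-67, and adjusted p = 0.0144 with an estimated correlation. Besides Cdkn1a, Ccng1 was higher by 3.002 ± 0.049, Eda2r by 3.43 ± 0.064 and Phlda3 by 3.08 ± 0.073. Mitotic genes went the other way: 28 of 30 were lower in clone 2 (0 higher and 28 lower adjusted over the list alone). The camera test gave adjusted p = 3.9e-21, and adjusted p = 0.0381 with an estimated correlation. Among them were Mki67 (-0.86 ± 0.048), Ccnb1 (-0.96 ± 0.056), Ube2c (-0.82 ± 0.054) and Ccna2 (-0.75 ± 0.049). These lists were the 2 of 48 that held with an estimated correlation. In the list of RNAs without a poly(A) tail 14 of 28 genes were lower (0 higher and 14 lower adjusted over the list alone). Tested with camera, the list had adjusted p = 0.00103, and adjusted p = 0.679 with an estimated correlation. Hist1h1d was at -0.65 ± 0.041, Hist1h3e at -0.63 ± 0.055, Hist2h4 at -0.57 ± 0.053 and Hist1h1b at -0.58 ± 0.057.

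**Figure D4:**
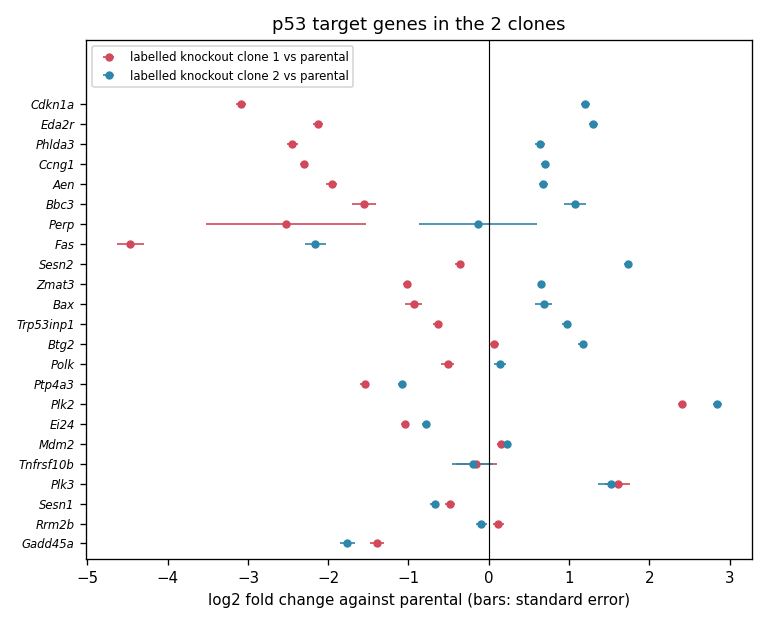
Log2 fold change against parental libraries of the 23 tested p53 target genes in each clone; points are the fitted values and bars the SE. Cdkn1a is at -3.09 in clone 1 and 1.205 in clone 2.

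Genes of glycolysis, hypoxia and the integrated stress response were higher in clone 2, and those of cholesterol synthesis were not. Of 19 glycolysis genes, 18 were higher and 1 lower (18 higher and 1 lower adjusted over the list alone). For these genes camera gave adjusted p = 3.5e-28, and adjusted p = 0.114 with an estimated correlation. Pgam1 was higher by 1.10 ± 0.042, Gpi1 by 1.09 ± 0.041, Tpi1 by 1.08 ± 0.044 and Pfkl by 1.33 ± 0.06. Hypoxia genes were higher in 15 of 19 cases and lower in 3 (15 higher and 3 lower adjusted over the list alone). Its camera adjusted p was 2.48e-10, and adjusted p = 0.0706 with an estimated correlation. Vegfa was higher by 1.06 ± 0.044, Pdk1 by 0.83 ± 0.047, Ndrg1 by 1.62 ± 0.095 and Ero1l by 0.79 ± 0.049. The nuclear genes of oxidative phosphorylation had 57 of 75 higher and 2 lower (63 higher and 2 lower adjusted over the list alone). Camera gave this list adjusted p = 5.76e-16, and adjusted p = 0.57 with an estimated correlation. After Ndufv3 the smallest p were those of Atp5g1 (0.75 ± 0.065), Ndufa8 (0.73 ± 0.076) and Uqcrc1 (0.38 ± 0.042). Integrated stress response genes were higher in 21 of 27 cases and lower in 4 (22 higher and 4 lower adjusted over the list alone). By camera the adjusted p was 2.58e-19, and adjusted p = 0.0706 with an estimated correlation. The smallest p were those of Sesn2 (2.10 ± 0.054), Asns (1.17 ± 0.051), Slc7a5 (0.88 ± 0.04) and Slc7a11 (0.92 ± 0.048). Of 16 genes of the mitochondrial unfolded protein response, 9 were higher and 1 lower (12 higher and 2 lower adjusted over the list alone). The camera test gave adjusted p = 0.01, and adjusted p = 0.617 with an estimated correlation. Atf5 was at 0.80 ± 0.069, Lonp1 at 0.64 ± 0.069, Hspa9 at 0.36 ± 0.044 and Afg3l2 at 0.52 ± 0.064. Of 24 genes of cholesterol synthesis, 2 were higher and 13 lower in clone 2 (2 higher and 13 lower adjusted over the list alone). Tested with camera, the list had adjusted p = 0.0826, and adjusted p = 0.58 with an estimated correlation. The list of the endoplasmic reticulum unfolded protein response had 3 of 24 genes higher and 10 lower (4 higher and 11 lower adjusted over the list alone). For these genes camera gave adjusted p = 0.333, and adjusted p = 0.617 with an estimated correlation. Of 13 protein genes of mitochondrial DNA 2 were lower and 11 did not pass (0 higher and 0 lower adjusted over the list alone).

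In the NRF2 list 14 of 25 genes were higher in clone 2 and 4 lower (14 higher and 4 lower adjusted over the list alone). Its camera adjusted p was 0.0353, and adjusted p = 0.49 with an estimated correlation. Tkt and Gstm1 were higher by 0.32 ± 0.04 and 0.32 ± 0.043, and Prdx1 was at -0.49 ± 0.051. Immediate early genes were lower in 12 of 21 cases and higher in 4 (4 higher and 12 lower adjusted over the list alone). Camera gave this list adjusted p = 2.88e-19, and adjusted p = 0.0706 with an estimated correlation. Fosb was at -2.50 ± 0.057, Egr3 at -1.91 ± 0.05, Nr4a1 at -2.18 ± 0.062 and Egr2 at -1.87 ± 0.058. Imprinted genes were lower in 13 of 20 cases and higher in 3 (3 higher and 13 lower adjusted over the list alone). By camera the adjusted p was 2.27e-07, and adjusted p = 0.249 with an estimated correlation. Peg10 and Peg3 were at -0.96 ± 0.052 and -0.80 ± 0.045. In the neural crest and Schwann list 6 of 10 genes were lower and 3 higher (3 higher and 7 lower adjusted over the list alone). The camera test gave adjusted p = 0.00591, and adjusted p = 0.26 with an estimated correlation. Ets1 was at -0.76 ± 0.044, Prrx1 at -0.44 ± 0.053 and Sox10 at 1.98 ± 0.21. Camera passed 12 lists in this comparison, 7 higher and 5 lower in clone 2.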

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

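The tests for a swap of single libraries, library depth, mixed astrocytes and growth factor signalling were chosen after the results were seen. Results below differ between the clones by the test of clone 2 against clone 1, and their values against parental cells, medians for lists, have opposite signs. Genes are given here only where they were also called against parental cells in each clone; the other differences between the clones are in the report. Of the lists, p53 targets had median log2 fold changes of -1.02 in clone 1 and 0.66 in clone 2 and a median clone difference of 1.61. Immediate early genes were at 0.54 and -0.42, with a difference of -0.68. Nuclear genes of oxidative phosphorylation were at -0.032 and 0.42, with a difference of 0.40. The mitochondrial unfolded protein response was at -0.13 and 0.051, with a difference of 0.25. Of these lists, p53 targets alone passed camera against parental cells in both clones, and they did not pass there with an estimated correlation (adjusted p = 0.0837 with an estimated correlation in clone 1 and 0.223 in clone 2). Camera did not pass for immediate early genes in clone 2 (adjusted p = 0.706, in the higher direction despite the median), oxidative phosphorylation in clone 1 (adjusted p = 0.921) or the mitochondrial list in clone 1 or 2 (adjusted p of 0.589 and 0.684).

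Among the genes named for the largest changes, 6 were lower than parental in clone 1 and higher in clone 2. Evc2 differed between the clones by 9.36 on the log2 scale, Evc by 5.04, Mxra7 by 4.62, Cdkn1a by 4.29, Trp53cor1 by 4.28 and Ndufv3 by 4.13. Dpp6 and Nrk were higher than parental in clone 1 and lower in clone 2, with differences of -7.42 and -5.98. Among the list members named, the p53 targets Eda2r (3.43), Phlda3 (3.08), Ccng1 (3.002) and Sesn2 (2.10) were lower in clone 1 and higher in clone 2, as were Sox10 (1.98), Pfkl (1.33), Atp5g1 (0.75), Ndufa8 (0.73), Lonp1 (0.64), Uqcrc1 (0.38) and Tkt (0.32). Fosb (-2.50), Nr4a1 (-2.18) and Peg3 (-0.80) went the other way.

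Mitotic genes were higher and astrocyte genes lower in the libraries labelled knockout, and the design gives the genotype as a biological explanation. A swap of single libraries between the groups is argued against, since 6 of 6 libraries correlated best with their own group, but an exchange of whole groups would leave that value as it is and stays open. Library depth is argued against, since the mean totals differed by a ratio of 1.07. Astrocytes mixed into parental cultures that otherwise match the labelled knockout ones stay open. The median mitotic gene was at 0.0268 of its labelled knockout level, with 0.0033 to 0.139 over the genes. This met a bound written against the explanation. That bound was written when the value was known, and it assumed a small share of astrocytes. A culture made up almost wholly of astrocytes would give this value too, and their share was not measured. Stronger growth factor signalling through ERK stays open too: the 10 genes of a MAPK activity score had a median log2 fold change of 2.9, but they were chosen after their values were seen and so do not support it, and culture conditions and the edit share the groups.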

How the results depend on the processing

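The count for labelled knockout against parental cells, 6532, was 6426 and 6455 under the other scalings, 6836 without a filter, 6865 with DESeq2, 6959 with limma-voom and 8268 with 6 libraries as replicates; every gene shared with these calls had the same direction. It was 4035 with an effect of at least 1 on the log2 scale, 3795 at 5 CPM or more, where fewer genes were tested, and 13213 for the averaged clone effects, where libraries were the replicates and the difference between the clones was taken out of the residual. Leaving out 1 library gave 2529 to 6714. The low end came without parental library 2, and 2544 without parental library 1; the fit then has 1 residual degree of freedom and the lone parental library is assumed to vary like the clones. With an effect of at least 1, clone 1 had 5084 calls, clone 2 had 5101, the clones against each other 1500, and 3680 genes were called in both; at 5 CPM or more the counts were 8019 for clone 1, 7847 for clone 2 and 5915 in both. Of 48 lists, 15 passed camera, 0 passed with an estimated correlation and 24 passed fry; the cause was not tested. For labelled knockout against parental cells and clone 2 against clone 1, the medians of the 27 list results past camera kept their sign under each scaling. The other lists were not run. Single genes were run only under DESeq2 size factors, DESeq2, 6 libraries as replicates and leaving out each library. They were mostly named for large changes or small p in these data, which favours keeping a side of the threshold. Of 196 results of single genes run under the alternatives, 175 kept direction and side of the threshold under each alternative run on them; 40 values were weaker, nearly all without a parental library, and 1 stronger, Epha4 under DESeq2 (adjusted p = 0.0244, with 0.0517 to 0.289 under the other alternatives).

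The library numbers were not taken to pair the samples. Deviations of same-numbered libraries correlated at -0.242 between parental and clone 1, -0.059 between parental and clone 2, and 0.267 between the clones. Each group gives a single deviation, so these values cannot settle whether libraries of the same number share a batch. With the library number as a replicate block the counts were 12659 for clone 1, 12412 for clone 2 and 8449 between the clones. For labelled knockout against parental, where the libraries of a clone were added, the block was the clone number in the titles. The count was then 6843. The titles do not say that a parental clone belongs with the knockout clone of the same number, and the block leaves fewer residual degrees of freedom. In simulated data 2.99% of 1.5-fold changes were called with the clones as replicates. Far fewer genes were changed there than were called in the real data, so this share cannot be carried over to them. In the real data 35 of 54 ribosomal protein genes were called higher, with a list median of 0.47 on the log2 scale. A small change that was not called still cannot be read as absent.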

Other observations

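The tests for the library kit and growth factor signalling were chosen after the results were seen. In the lysosome list 9 of 34 genes rose and 7 fell in labelled knockout cells (12 higher and 8 lower adjusted over the list alone). Tested with camera, the list had adjusted p = 0.988, and adjusted p = 0.996 with an estimated correlation. Cln3, the gene of juvenile Batten disease, dropped from 25.6 ± 0.62 CPM to 0.322 ± 0.0842 and 0.284 ± 0.0808 (-6.37, SE 0.16, adjusted p = 0.00013). Ctsz changed by -3.23 ± 0.18 and Ctsb by -1.44 ± 0.089, while Naglu rose by 1.87 ± 0.12.

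Of the 10 MAPK score genes, 7 rose and 3 did not pass. Dusp6, a phosphatase that ERK induces against itself, rose 27.7-fold, Spry4 23-fold, and the ETS factor genes Etv4 and Etv5 15.6-fold and 10.4-fold. Spry2, Dusp4 and Ccnd1 had log2 fold changes of 2.05, 2.64 and 3.15, and Phlda1, Epha4 and Epha2, which did not pass, of -0.36, -0.69 and 0.52.

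Gene models of satellite repeats were higher in the parental libraries: 12 models held 2315 to 2430 CPM there and 39.3 to 58.8 CPM in the labelled knockout libraries, 45.7-fold by the means, led by Gm10800 (GRCm38 chromosome 2, 98666547 to 98667301). A kit that keeps other RNA classes stays open. Rn7sk, which has no poly(A) tail, differed by only 0.0521 on the log2 scale. It is a single RNA, and its bound was written after the results were seen. In the list of RNAs without a poly(A) tail, mostly histone genes made in S phase, 26 of 28 were higher in labelled knockout cells. For genomic DNA, a bound set beforehand was met: the summed CPM of olfactory and vomeronasal receptor genes, parental over labelled knockout, was 0.922, under 1.5 in every pair. That sum does not settle it, because 3 receptor models held 51.3% to 56.0% of these counts in labelled knockout libraries and 18.6% to 20.5% in parental ones; 1093 receptor models with under 60 counts in all held 3.25 times as much CPM in parental libraries, a check added after this was seen. Genomic DNA, a kit difference and transcription of the repeats therefore cannot be told apart, and no biological explanation was tested.

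Genes of chromosomes 11 and 15 were shifted in the median: 794 genes of chromosome 11 had a median of 0.24 on the log2 scale from clone 1 to clone 2, against -0.14 to 0.03 for the other autosomes, and 394 genes of chromosome 15 had -0.23 from parental cells to the mean of the clones, against -0.02 to 0.12. Bias by GC content is argued against, since genes of other autosomes matched on GC content and expression had medians of -0.00634 and 0.0234, within -0.0465 to 0.0188 and -0.0465 to 0.0812 over 100 draws. A gain of chromosome 11 in part of the cells of clone 2 may account for the former shift. A dosage of chromosome 15 that differs between the parental cells and both clones may account for the latter, on whichever side it arose. On the side of the shift lay 11 of 13 windows of 10 Mb (84.6%) and 8 of 9 (88.9%), short of the 90% set beforehand. With so few windows the miss is narrow and decides little. Such changes of dosage therefore cannot be told apart from regional changes of expression.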
